A study of Mus musculus with 13 samples.

How the data were processed

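RNA of 13 libraries, each from 50000 sorted CD138-positive, B220-negative, CD45.2-positive bone marrow cells of mice, was analysed in 6 groups and 4 arms (WT 3, V 3, tVk12653 2, and VQ 5 from lines D1, D4 and D5). RNA was extracted with the RNeasy Micro kit and libraries were made with a SMARTer stranded total RNA kit for picogram input, per the labels. The submitters' processing notes name STAR 2.6.1d and genome build GRCm38.p6. The deposited table holds raw read counts per gene symbol for each library, without normalization. The counting tool, the annotation, the strand setting and the handling of reads with several alignments are not given in the sources used here. The table has 22997 symbols, of which 22000 matched the RefSeq annotation of GRCm38.p6 and 997 did not, and 2713 had no count in any library. It holds no immunoglobulin or T cell receptor gene segments, so segment shares and alternatives without these segments were not run. Sequence reads were not analysed here.

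Total counts per library were 2096815 to 8512281. The 10 most abundant genes of a library held 7.61 to 18.2% of its counts and mitochondrial genes 1.24 to 2.49%. A floor of 3 counts equals 0.326 to 1.49 CPM, depending on the library. For a gene at 0 in every library of an arm the fold change is given as a lower bound against that floor in each library. These floors cover counting error alone: between libraries of 1 group the chi-square per degree of freedom was 5.23 to 15.6, where counting error alone gives about 1.

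The tests, samples, covariates, lists and named-gene rule were set before the data were examined. Counts were normalized with trimmed means of M values (TMM), genes were filtered with filterByExpr (minimum count 10, minimum total 15), and arms were compared with edgeR 4.0.16 quasi-likelihood tests (robust) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 11 units were the WT, V and tVk12653 libraries and the 3 VQ lines, with the counts of the recipients of a line summed. D1 and D5 were compared in a fit of all 13 libraries with 1 mean per group. The common biological coefficient of variation was 0.409 in the fit of arms and 0.195 in the fit of groups. CPM of arms, and of lines given with them, is scaled by the factors of the fit of arms. CPM of single libraries, values of the blocked V and WT fit, silent genes, chromosome shifts and lower bounds of fold changes use per-library scaling, so the same gene can have slightly different values.

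Gene lists numbered 27, 18 of pathways (proliferation, DNA replication, MYC targets, RAS-ERK output, plasma cell identity, unfolded protein response, ATF4 response, glycolysis, oxidative phosphorylation, MHC class I, MHC class II, interferon response, checkpoint ligands, NF-kB targets, p53 targets, BCL2 family, adhesion and myeloma genes) and 9 of cell markers (neutrophils, monocytes, T and NK cells, B cells, erythroid cells, megakaryocytes, stroma, basophils and dendritic cells). Each was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01 and again with the correlation estimated, and its genes were also adjusted over the list alone. Genes named by this rule were, first, the 8 largest changes per direction (5 for D1 against D5). These had an adjusted p under 0.05, a mean log2 CPM of at least 3 in the higher arm and no overlap between arms. Up to 4 genes per list were also named, which needed only an adjusted p under 0.05. Myc, Nras, Sdc1, Ptprc and the 3 most abundant genes of each marker list were named whatever their values. Where no gene of a list passed, its 2 most abundant genes were eligible. Sex-linked genes, the blocked V and WT genes and the silent genes were named after seeing the data. Segment, predicted, ribosomal protein, histone, mitochondrial, small RNA and marker genes were not eligible for the largest changes. Results for a few single genes are not reported here.

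The alternatives were relative log expression factors, no low count filter, a stricter filter (30 counts), DESeq2 1.42.0, fits of the 2 arms alone, all libraries with a mean per arm or per group, a replicate block, a fold threshold, removal of the 20 most abundant genes, and each library or VQ line left out. Added after seeing the data were removal of X and Y genes, WT replicate 2 and D1 replicate 1 both left out, a fit without the VQ lines, and a block in a fit of V and WT alone, with all pairs or each left out. To check pairing, deviations from the group mean were correlated between libraries of different groups, after the call counts with the block had been seen. Libraries of WT and V with the same number had r of 0.209 to 0.265 and those with different numbers -0.196 to -0.0857, and for no other pair of groups were all same-number values over 0.1.

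The tests were run on simulated data with 100 genes changed by 2-fold and 100 by 4-fold. They recovered 4% and 57% of them in V against WT, 10% and 60% in VQ against WT, 2% and 43% in tVk12653 against WT, 8% and 62% in VQ against V, 2% and 57% in VQ against tVk12653 and 44% and 76% in D1 against D5, none in the wrong direction. With the spread of V and WT alone the values were 59% and 94%, and with the block 59% and 92% with 12 false calls. Camera called 1 shifted list and 0 others of 20 simulated lists. The simulated genes were drawn independently, so this cannot show how camera does on lists of correlated genes. Shifts of whole chromosomes used 10130 genes of at least 5 CPM. On simulated data with 10145 such genes a shift of -1 was recovered as -0.965 to -0.954. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.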

Results

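Bulk RNA sequencing profiled plasma cells of the bone marrow from normal mice and from mouse models of multiple myeloma, the cancer of plasma cells. Each of the 13 libraries was made from 50000 sorted cells that carried CD138 (syndecan-1, a plasma cell surface protein) and CD45.2 and lacked B220. WT was 3 libraries from wild-type mice. V was 3 libraries from mice with the Vκ*MYC transgene, which carries human MYC that is switched on in germinal centre B cells, and with Cre expressed from the IgG1 locus. VQ added an Nras allele that Cre turns into its activated mutant form, and its 5 libraries came from recipients of 3 transplanted lines, D1 (2 recipients), D4 (1) and D5 (2). tVk12653 was 2 libraries from recipients of a single transplantable Vκ*MYC line. VQ and tVk12653 cells came from transplant recipients and WT and V cells did not, so genotype and transplantation cannot be told apart in any comparison across these arms. Total counts were 2948892, 2575570 and 3640249 in WT, 2096815, 2925097 and 3257813 in V, and 4126625 and 2880511 in tVk12653. The VQ totals were 3401667 and 8512281 in D1, 7403425 in D4, and 3754964 and 3935069 in D5. Levels are CPM (counts scaled to a common library size) as mean ± SD over 3 WT, 3 V or 2 tVk12653 libraries, with each VQ line given separately. Log2 fold changes are given ± standard error, and p-values are from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment. For each list, the counts of genes higher and lower that passed when adjusted over the list alone stand beside those adjusted over all genes.

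The engineered genes and the sort markers differed between groups and lines. Myc (GRCm38.p6 chromosome 15, 61985341 to 61990361) stood at 51.8, 72.8 and 35.0 CPM in the WT libraries, 309, 430.4 and 364 in V, 903 and 686 in VQ D1, 1647 in D4, 1346 and 1663 in D5, and 8006 and 8214 in tVk12653. How many reads of the human transgene were counted on the mouse gene is not known. Nras (chromosome 3, 103058285 to 103067914) stood at 36.9, 36.4 and 36.1 CPM in WT, 35.7, 38.1 and 30.8 in V, 45.6 and 41.7 in D1, 59.2 in D4, 132 and 163 in D5, and 54.1 and 46.8 in tVk12653, and gene counts do not tell its mutant and normal alleles apart. Sdc1, which encodes CD138, lay between 364 CPM (a D5 recipient) and 1424 CPM (D4). Ptprc (chromosome 1, 138062859 to 138175756), which encodes CD45, stood at 547, 800.0 and 604 CPM in WT and 585, 586 and 506 in V, but at 1.68 CPM in D4 and 1.85 and 6.63 CPM in D5. Sex-linked RNA differed too: Xist, expressed from the inactive X chromosome, stood at 2648, 1494 and 1880.4 CPM in V, 1492 in WT replicate 1 and at most 3.98 in the other WT libraries, while the Y-linked Ddx3y was at 0 in V and at 48.2, 129.7 and 141 CPM in WT. S100a9, an abundant neutrophil RNA, stood at 903, 2527 and 973 CPM in WT, 509, 1054 and 567 in V, 273 and 80.9 in D1, 14.9 in D4, 12.7 and 25.5 in D5, and 35.2 and 20.7 in tVk12653. Libraries of the same group had Spearman correlations of 0.953 to 0.987, V and WT libraries of 0.911 to 0.976, and libraries of different VQ lines of 0.832 to 0.900. The leading principal component held 46.9% of the variance and placed all WT and V libraries at -99.1 to -69.2 and all VQ and tVk12653 libraries at 51.4 to 90.5.

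**Figure D1:**
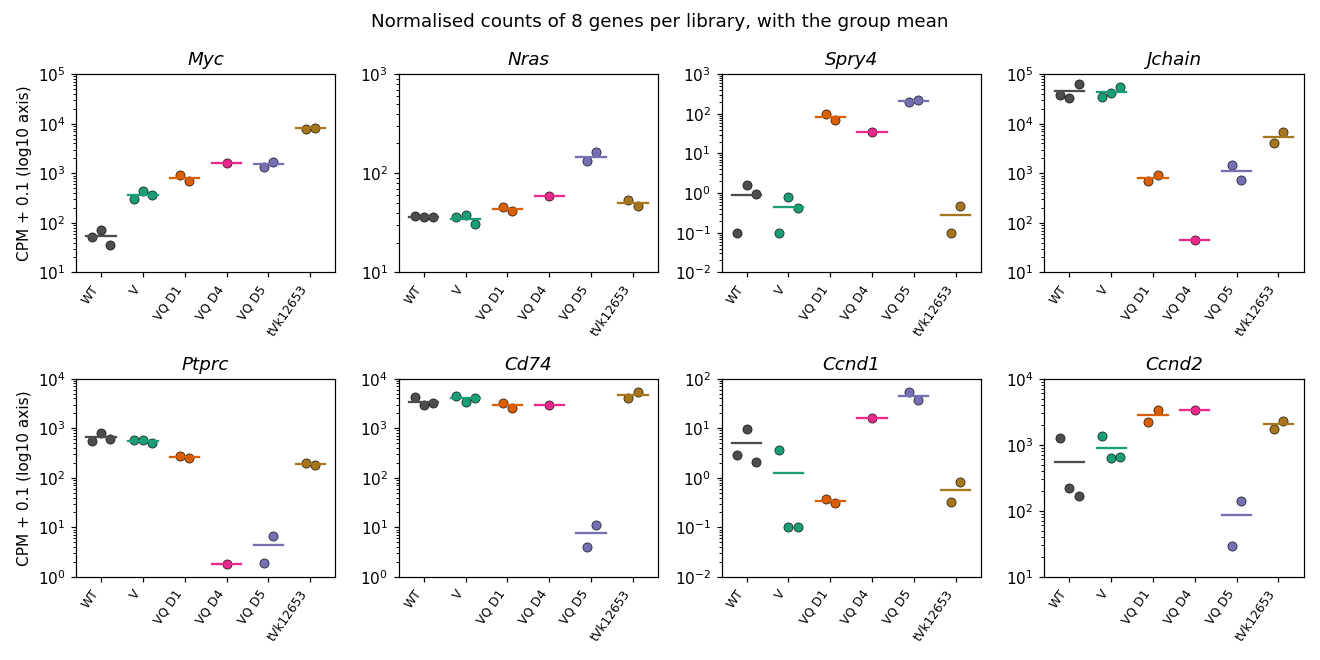
Normalised counts (CPM with a small constant added, log10 axis) of Myc, Nras, Spry4, Jchain, Ptprc, Cd74, Ccnd1 and Ccnd2 in each library (points) with the group mean (lines), by group on the horizontal axis. Myc lay highest in tVk12653 (8006 and 8214 CPM), Spry4 was at least 34.6 CPM in every VQ library and at most 1.49 CPM in every other library, and Ptprc was lowest in VQ D4 (1.68 CPM) and Cd74 in VQ D5 (3.96 and 11.2 CPM).

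V against WT sets plasma cells with the MYC transgene and Cre against normal ones, and the sex-linked RNA differed between these arms as well. Myc stood at 363 ± 58.5 CPM in V and 52.0 ± 18.6 CPM in WT, and each V library exceeded each WT library (log2 fold change 2.80 ± 0.35, adjusted p = 0.0852 in the fit of all arms). Of 2 plasma cell genes, Jchain, the joining chain of secreted antibody, stood at 43163 ± 9933 CPM in V and 44151 ± 16388 in WT, and Irf4, a transcription factor that plasma cells need, at 1815 ± 52.7 and 1350.5 ± 411 CPM. In the fit of all arms edgeR called 0 genes higher and 0 lower of 11933, and DESeq2 called 10 higher and 32 lower. In that edgeR fit 628 genes had an unadjusted p under 0.05, about the share that chance alone would give. WT and V libraries with the same replicate number deviated together. A fit of all 13 libraries with 1 mean per group called 17 genes higher and 7 lower, and 43 and 48 with that number as a block. The block in a fit of these 2 arms alone, which was chosen after seeing the data, called 138 genes higher and 341 lower.

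In the blocked fit of the 2 arms, Myc rose (log2 fold change 2.84 ± 0.17, adjusted p = 2.26e-05). Csn3, the milk protein kappa-casein, rose by 3.96 ± 0.36, adjusted p = 1.52e-04, and Cp, the copper-carrying ferroxidase ceruloplasmin, by 3.00 ± 0.24, adjusted p = 6.57e-04. Esyt3 (3.52 ± 0.46), Mgarp (3.02 ± 0.52), Gprc5b (2.52 ± 0.38), Upb1 (1.38 ± 0.31) and Ly6k (1.81 ± 0.37) also rose. Among the genes that fell were Nr4a1, an immediate early nuclear receptor (-4.27 ± 0.30, adjusted p = 2.26e-05), Adgrg1 (-3.94 ± 0.41) and Trim10 (-3.89 ± 0.75). The haemoglobin gene Hbb-b1 went from 32.0 to 0.443 CPM (per-library scaling, adjusted p = 9.47e-04). The Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d fell as well, and 4 of the called genes lie on Y and 15 on X. Of the 16 genes named here, 9 also passed with the block in the fit of all libraries. There Nr4a1 (adjusted p = 0.0977), Adgrg1 (0.0580), Trim10 (0.101), Hbb-b1 (0.139), Gprc5b (0.310), Upb1 (0.156) and Ly6k (0.0606) did not pass. Leaving out a pair, also chosen after seeing the data, gave 211 genes higher and 480 lower without pair 1, 47 and 85 without pair 2, and 124 and 478 without pair 3, with 15, 14 and 14 of the named genes called.

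The lists in that blocked fit of the 2 arms moved as follows. Proliferation genes fell in 11 of 27 cases (0 and 18 over the list alone, camera adjusted p = 1.05e-12, adjusted p = 0.439 with an estimated correlation). DNA replication genes fell in 9 of 28 (0 and 12 over the list alone, camera adjusted p = 6.13e-10, adjusted p = 0.439 with an estimated correlation). Neutrophil markers fell alongside in 11 of 19 (0 and 15 over the list alone, camera adjusted p = 9.10e-12, adjusted p = 0.439 with an estimated correlation). Erythroid markers fell in 7 of 11 (0 and 10 over the list alone, camera adjusted p = 3.77e-11, adjusted p = 0.439 with an estimated correlation). ATF4 and amino acid response genes rose in 5 of 17 cases (11 and 0 over the list alone, camera adjusted p = 2.90e-06, adjusted p = 0.439 with an estimated correlation). None of the 30 MYC target genes for ribosome biogenesis and nucleotide synthesis passed either way, although their set test was called (camera adjusted p = 0.00909, adjusted p = 0.576 with an estimated correlation). Of unfolded protein response genes 2 of 22 rose (5 and 0 over the list alone, camera adjusted p = 2.01e-05, adjusted p = 0.576 with an estimated correlation). Of oxidative phosphorylation genes 0 of 28 rose (0 and 0 over the list alone, camera adjusted p = 7.89e-05, adjusted p = 0.439 with an estimated correlation), and of MHC class I genes 1 of 15 (8 and 0 over the list alone, camera adjusted p = 1.85e-05, adjusted p = 0.439 with an estimated correlation). Camera also called plasma cell identity genes (2 higher and 1 lower of 22, 2 and 1 over the list alone, camera adjusted p = 0.0222, adjusted p = 0.576 with an estimated correlation) towards higher values in V. It called p53 targets the same way (1 higher and 1 lower of 15, 1 and 1 over the list alone, camera adjusted p = 0.0373, adjusted p = 0.576 with an estimated correlation). RAS-ERK output genes (2 of 11 lower, 0 and 2 over the list alone, camera adjusted p = 0.00333, adjusted p = 0.576 with an estimated correlation) and monocyte markers (1 of 12 lower, 0 and 5 over the list alone, camera adjusted p = 1.37e-06, adjusted p = 0.439 with an estimated correlation) were called towards lower values. Of 82 ribosomal protein genes 26 rose (16 with the block in the fit of all libraries). Of 9 immediate early genes 5 fell (Nr4a1, Junb, Ier2, Zfp36 and Dusp1), but 0 passed with the block in the fit of all libraries (adjusted p = 0.0977 to 0.518), and both sets were picked after their values were seen. Interferon response genes had a median of 0.40 and a mean of -0.10 in the fit of all arms, so they had no single direction. None of these set calls held with a correlation estimated from the data. With the block in the fit of all libraries, 2 proliferation, 2 DNA replication, 3 erythroid and 0 neutrophil genes were lower and 0 ATF4 genes were higher. The neutrophil gene S100a9 was at 903, 2527 and 973 CPM in WT replicates 1, 2 and 3. Without pair 2, 2 proliferation, 0 DNA replication and 7 neutrophil genes were lower, and the set calls of MYC targets (camera adjusted p = 0.218), plasma cell identity and p53 targets (0.277) were lost. Without pair 1, 2 or 3 the ATF4 genes higher were 8, 2 and 3, the unfolded protein response genes 1, 0 and 0 and the MHC class I genes 2, 0 and 2. The immediate early genes lower were 9, 5 and 6, the ribosomal protein genes higher 23, 7 and 15 and the monocyte markers lower 4, 2 and 4. The set call of RAS-ERK genes was lost without pair 1 (camera adjusted p = 0.0663). In the fit of all arms, with WT replicate 2 and D1 replicate 1 left out, the median log2 fold change went from -0.67 to -0.22 for proliferation, from -0.52 to -0.22 for DNA replication and from -1.15 to -0.48 for neutrophil markers. The simulated recovery of 2-fold changes was 4% in the fit of all arms. With the spread of V and WT alone it was 59% with the block (12 false calls) and 59% without it (3 false calls). Only the simulation with the block held a shift shared by libraries of the same number, so these values do not show a gain from the block. In the fit of all arms without WT replicate 2, 253 of 11841 genes had an unadjusted p under 0.05, a smaller share than chance alone would give.

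VQ against WT asks how plasma cell tumours with MYC and mutant Nras differ from normal plasma cells. The tumour lines held far more Myc RNA (766, 1621 and 1589 CPM in D1, D4 and D5 against 52.0 ± 18.6 CPM, log2 fold change 4.67 ± 0.38, adjusted p = 8.77e-05). They held somewhat more Nras too (43.8, 58.2 and 156 against 35.6 ± 0.335 CPM, 1.27 ± 0.40, adjusted p = 0.0362). Most genes listed for ribosome biogenesis and oxidative phosphorylation rose, and genes of the MHC class II and NF-kB lists fell more often than they rose. In all, edgeR called 2065 genes higher and 1807 lower of 11933, of which 1444 and 1444 changed at least 2-fold. The balance of directions depended on the scaling, with 1831 higher and 1967 lower by relative log expression factors. Among the largest rises, Spats2 went from 0.115 CPM in WT to 151, 211 and 114 CPM in the lines (adjusted p = 5.33e-04). Lin28b, an RNA-binding protein that blocks let-7 microRNA, went from 0.0926 to 88.6, 50.4 and 5.47 CPM (adjusted p = 0.00216). Slc47a1, a transporter of organic cations, was at 0 in every WT library and at least 21.7-fold higher in VQ at a floor of 3 counts per library. Lamb1, a laminin chain of the basement membrane (7.82 ± 0.97), rose. Fam20a went from 0.461 CPM in WT to 146, 56.8 and 21.5 CPM, Fkbp10 from 0.364 to 69.1, 58.4 and 26.0 CPM, and the calcium channel subunit Cacnb3 from 0.364 to 33.7, 73.5 and 34.5 CPM. Of the largest falls, Cd79a, the signalling chain of the B cell receptor, went from 277 ± 106 CPM to 0, 0 and 0.684 CPM (adjusted p = 8.55e-05). Clec2g and Cd200, a ligand that restrains myeloid cells, were at 0 in every VQ library, at least 65.9-fold and 42.2-fold lower than in WT. P2ry10, the protease inhibitor Serpina3f and the activation marker Cd83 fell from 80.2, 89.5 and 57.3 CPM to under 1 CPM in each line, and the Y-linked Uty and Ddx3y were also among the largest falls.

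The gene lists gave the following account of the VQ lines. MYC target genes for ribosome biogenesis and nucleotide synthesis rose in 27 of 30 cases and fell in 0 (28 and 0 over the list alone, camera adjusted p = 1.63e-12, adjusted p = 0.240 with an estimated correlation). Among them were the nucleolar genes Nhp2 (2.90 ± 0.41) and Npm1 (2.43 ± 0.39) and the polyamine enzyme Srm (2.48 ± 0.35). Oxidative phosphorylation genes rose in 23 of 28 (23 and 0 over the list alone, camera adjusted p = 1.52e-08, adjusted p = 0.178 with an estimated correlation), with the ATP synthase genes Atp5g1 (1.68 ± 0.32) and Atp5b (1.31 ± 0.20) as examples. Proliferation genes rose in 11 of 28 (20 and 0 over the list alone, camera adjusted p = 1.89e-05, adjusted p = 0.418 with an estimated correlation), led by the mitotic regulators Cdc20 (2.98 ± 0.76) and Ube2c (2.36 ± 0.74). DNA replication genes rose in 8 of 28 (8 and 0 over the list alone, camera adjusted p = 0.00184, adjusted p = 0.491 with an estimated correlation), led by Rfc4 (2.38 ± 0.65). Of the RAS-ERK output list 5 rose and 1 fell of 18 (5 and 1 over the list alone, camera adjusted p = 0.0652). Spry4 (chromosome 18, 38586247 to 38601347), an inhibitor that the pathway itself induces, went from 0.763 ± 0.730 CPM to 79.6, 34.1 and 222 CPM (7.16 ± 0.97, adjusted p = 8.69e-04). The transcription factors Etv4 and Etv5 rose too, Etv4 from 0.185 to 9.51, 13.5 and 41.5 CPM and Etv5 from 10.1 to 43.0, 72.6 and 210.0 CPM. Egr2, an immediate early gene of the same list, fell (-5.64 ± 1.12). Plasma cell identity genes fell in 8 of 22 cases and rose in 1 (2 and 10 over the list alone, camera adjusted p = 0.00255, adjusted p = 0.240 with an estimated correlation). Jchain (chromosome 5, 88519809 to 88527897) fell from 44151 ± 16388 CPM to 891, 43.7 and 1167 CPM (-5.98 ± 1.01, adjusted p = 0.00244), and Cd38, an ectoenzyme of plasma cells, from 22.9 ± 2.59 to 0.158, 0 and 1.64 CPM. MHC class II genes fell in 6 of 10 (0 and 6 over the list alone, camera adjusted p = 9.52e-04, adjusted p = 0.276 with an estimated correlation), including the chains H2-Aa (-7.10 ± 0.94) and H2-Ab1 (-5.84 ± 0.71). None of the 15 MHC class I genes passed (0 and 0 over the list alone, camera adjusted p = 0.520). NF-kB targets fell in 10 of 16 (0 and 10 over the list alone, camera adjusted p = 1.89e-05, adjusted p = 0.240 with an estimated correlation), Nfkb2 at -2.39 ± 0.66. The lines differed here: D1 minus D5 medians were 2.78 for the MHC class II list and 2.99 for NF-kB targets. Interferon response genes fell in 6 of 22 with 1 higher (1 and 6 over the list alone, camera adjusted p = 0.00436, adjusted p = 0.418 with an estimated correlation), Irf7 at -1.92 ± 0.49. ATF4 and amino acid response genes rose in 8 of 17 and fell in 1 (10 and 1 over the list alone, camera adjusted p = 0.0142, adjusted p = 0.418 with an estimated correlation), with the serine synthesis enzyme Psat1 at 2.66 ± 0.26. Glycolysis genes rose in 6 of 16 and fell in 1 (6 and 1 over the list alone, camera adjusted p = 0.0432, adjusted p = 0.418 with an estimated correlation), Ldha at 2.00 ± 0.37. Genes of the p53 list rose in 8 of 17 and fell in 1 (8 and 1 over the list alone, camera adjusted p = 0.00279, adjusted p = 0.240 with an estimated correlation). They included the cell cycle inhibitor Cdkn1a (3.15 ± 0.70) and Zmat3 (2.42 ± 0.34). Adhesion and homing genes fell in 9 of 21 and rose in 1 (1 and 10 over the list alone, camera adjusted p = 7.17e-04, adjusted p = 0.213 with an estimated correlation). Proliferation genes higher numbered 0 without WT replicate 1, 0 without WT replicate 3 and 23 without D4. DNA replication genes higher numbered 2 without WT replicate 1, 2 without WT replicate 3 and 21 without D4. Identity genes of plasma cells lower numbered 14 without D4. Oxidative phosphorylation genes higher numbered 15 without WT replicate 3. NF-kB targets lower numbered 6 without WT replicate 1, 4 without WT replicate 2 and 5 without WT replicate 3. Interferon response genes lower numbered 10 without D1 replicate 2. ATF4 genes higher numbered 3 without WT replicate 2 and 3 without WT replicate 3.

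In VQ against WT, unfolded protein response and chaperone genes rose in 6 and fell in 2 of 22 (7 and 2 over the list alone, camera adjusted p = 0.0652), with the disulphide isomerase Pdia6 higher (1.44 ± 0.28) and Dnajb9 lower (-1.24 ± 0.24). Checkpoint ligands rose in 3 and fell in 5 of 13 (3 and 6 over the list alone, camera adjusted p = 0.0399, adjusted p = 0.240 with an estimated correlation). Cd276 (B7-H3) went from 0.479 to 3.88, 16.7 and 59.4 CPM and Pdcd1lg2 (PD-L2) from 22.2 to 0.158, 0.690 and 0 CPM. Among the BCL2 family 2 rose and 1 fell of 12 (2 and 0 over the list alone, camera adjusted p = 0.791), Bcl2 itself at -2.88 ± 0.98, though D1 held more Bcl2 than D5. Myeloma genes rose in 5 and fell in 3 of 19 (6 and 3 over the list alone, camera adjusted p = 0.404), the transcription factor Maf at -3.83 ± 0.60. Markers of other cells were lower in VQ beside all of these groups. Neutrophil markers fell in 17 of 19 (0 and 18 over the list alone, camera adjusted p = 7.39e-09, adjusted p = 0.240 with an estimated correlation). B cell markers fell in 14 of 16 (0 and 14 over the list alone, camera adjusted p = 4.17e-09, adjusted p = 0.178 with an estimated correlation). Erythroid markers fell in 12 of 13 (0 and 12 over the list alone, camera adjusted p = 1.18e-06, adjusted p = 0.240 with an estimated correlation). Monocyte markers fell in 13 of 17 (0 and 13 over the list alone, camera adjusted p = 3.17e-06, adjusted p = 0.240 with an estimated correlation). T and NK cell markers fell in 9 of 11 (0 and 9 over the list alone, camera adjusted p = 1.20e-04, adjusted p = 0.240 with an estimated correlation). Dendritic cell markers fell in 4 of 8 (0 and 4 over the list alone, camera adjusted p = 0.00279, adjusted p = 0.178 with an estimated correlation). Basophil and mast cell markers fell in 3 of 3 (0 and 3 over the list alone, camera adjusted p = 0.0104, adjusted p = 0.240 with an estimated correlation). Megakaryocyte markers fell in 2 of 3 (0 and 2 over the list alone, camera adjusted p = 0.0388, adjusted p = 0.290 with an estimated correlation). Stroma and endothelium markers fell in 3 of 6 (1 and 3 over the list alone, camera adjusted p = 0.108). Unfolded protein response genes higher numbered 1 without WT replicate 2. Checkpoint ligands lower numbered 3 without WT replicate 2. Myeloma genes higher numbered 3 without WT replicate 3. Monocyte markers lower numbered 6 without WT replicate 2. T and NK cell markers lower numbered 5 without WT replicate 1 and 5 without WT replicate 2. All genes called higher numbered 1358 without WT replicate 1 and 1140 without WT replicate 3.

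**Figure D2:**
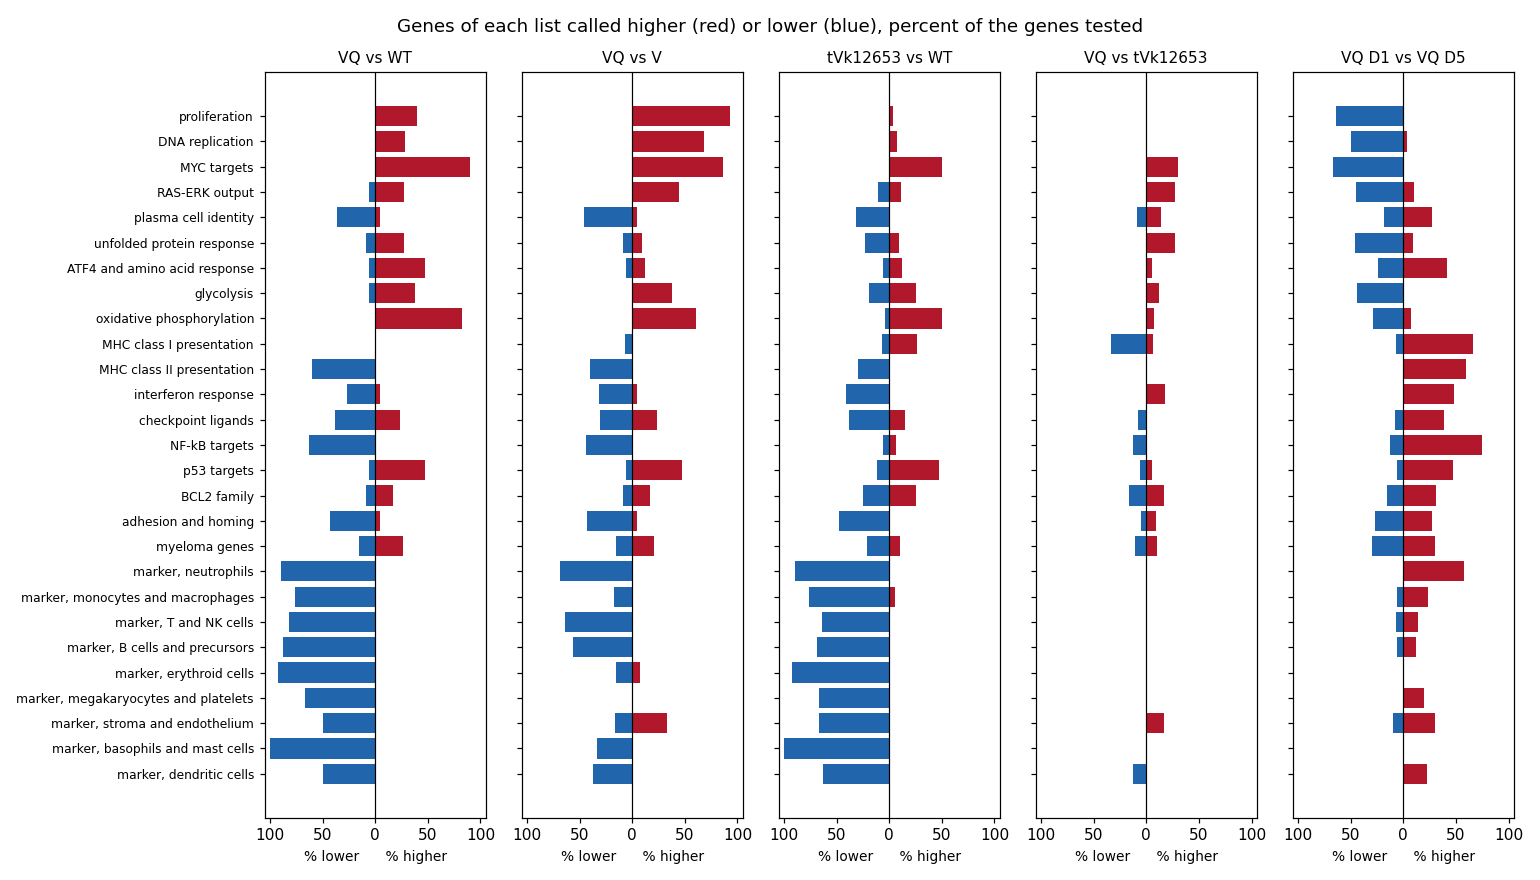
Percent of the tested genes of each list that edgeR called higher (red, to the right) or lower (blue, to the left), for 27 lists (vertical axis) and 5 comparisons (panels). MYC targets rose in 27 of 30 in VQ against WT and fell in 20 of 30 in VQ D1 against VQ D5, and markers of other cells lay on the lower side in VQ and tVk12653 against WT.

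VQ against V sets tumours with the added Nras allele against plasma cells that carry the MYC transgene without it. Most listed proliferation genes rose, and more of the listed plasma cell and B cell genes fell than rose. edgeR called 1865 genes higher and 1474 lower of 11933. Myc was higher still in VQ than in V (1.87 ± 0.33, adjusted p = 0.00379), and so was Nras (1.32 ± 0.40, adjusted p = 0.0358). Proliferation genes rose in 26 of 28 cases (28 and 0 over the list alone, camera adjusted p = 4.65e-09, adjusted p = 0.375 with an estimated correlation). DNA replication genes rose in 19 of 28 (22 and 0 over the list alone, camera adjusted p = 2.86e-06, adjusted p = 0.411 with an estimated correlation). Examples were the mitotic spindle gene Tpx2 (2.85 ± 0.63), Cdc20 (3.34 ± 0.78) and the helicase loader Cdc6 (2.73 ± 0.76). MYC targets rose in 26 of 30 (28 and 0 over the list alone, camera adjusted p = 5.07e-12, adjusted p = 0.283 with an estimated correlation), Nop58 at 2.11 ± 0.26. Oxidative phosphorylation genes rose in 17 of 28 (18 and 0 over the list alone, camera adjusted p = 5.59e-06, adjusted p = 0.266 with an estimated correlation). RAS-ERK output genes rose in 8 of 18 with 0 lower (9 and 0 over the list alone, camera adjusted p = 0.00110, adjusted p = 0.339 with an estimated correlation). Spry4 went from 0.340 CPM in V to 79.6, 34.1 and 222 CPM, Etv4 from 0.270 to 9.51, 13.5 and 41.5 CPM, the receptor Epha2 from 0.514 to 7.29, 41.4 and 41.2 CPM, and Spry1, at 0 in every V library, was at least 6.81-fold higher. Plasma cell identity genes fell in 10 of 22 (1 and 10 over the list alone, camera adjusted p = 1.81e-04, adjusted p = 0.266 with an estimated correlation), Jchain at -5.95 ± 1.00, adjusted p = 0.00316. Interferon response genes fell in 7 of 22 and rose in 1 (1 and 7 over the list alone, camera adjusted p = 0.00110, adjusted p = 0.392 with an estimated correlation). NF-kB targets fell in 7 of 16 (0 and 9 over the list alone, camera adjusted p = 2.32e-05, adjusted p = 0.283 with an estimated correlation). MHC class II genes fell in 4 of 10 (0 and 4 over the list alone, camera adjusted p = 0.00295, adjusted p = 0.375 with an estimated correlation). Genes of this list and of the NF-kB list were mostly higher in D1 than in D5. Adhesion genes fell in 9 of 21 (1 and 9 over the list alone, camera adjusted p = 0.00124, adjusted p = 0.266 with an estimated correlation), such as the homing integrin chain Itgb7 (-3.60 ± 0.48). Genes of the p53 list rose in 8 of 17 and fell in 1 (10 and 2 over the list alone, camera adjusted p = 0.0153, adjusted p = 0.375 with an estimated correlation). Glycolysis genes rose in 6 of 16 (6 and 0 over the list alone, camera adjusted p = 0.0487, adjusted p = 0.442 with an estimated correlation). Uaca (6.97, 8.55 and 310.4 CPM against 0.106) and Eya4 (0.871, 37.8 and 125 against 0.164) were among the largest rises, with D5 the highest line for both. Serpina3g and Trib2 fell from 64.8 and 38.0 CPM to under 1 CPM in each line, and Clec2g and the interleukin-9 receptor Il9r, at 0 in every VQ library, were at least 151-fold and 19.6-fold lower. Neutrophil markers fell in 13 of 19 (0 and 16 over the list alone, camera adjusted p = 4.52e-07, adjusted p = 0.375 with an estimated correlation). B cell markers fell in 9 of 16 (0 and 10 over the list alone, camera adjusted p = 1.73e-06, adjusted p = 0.266 with an estimated correlation). Erythroid markers fell in 2 and rose in 1 of 13 (1 and 2 over the list alone, camera adjusted p = 0.171). Among the other marker lists, median log2 fold changes were -3.22 for T and NK cells, -2.01 for monocytes and -2.15 for dendritic cells. They were -2.77 for basophils, -1.40 for megakaryocytes and 0.06 for stroma. The counts depended on single V libraries: without V replicate 1, 2 or 3 the genes higher were 1002, 1140 and 857 and those lower 910, 978 and 837. Proliferation genes higher numbered 7 without V replicate 1 and 4 without V replicate 3. DNA replication genes higher numbered 6 without V replicate 1 and 5 without V replicate 3. Oxidative phosphorylation genes higher numbered 10 without V replicate 1 and 10 without V replicate 3. Identity genes of plasma cells lower numbered 5 without V replicate 3. Interferon response genes lower numbered 3 without V replicate 1. NF-kB targets lower numbered 3 without V replicate 1, 3 without V replicate 2 and 3 without V replicate 3. MHC class II genes lower numbered 2 without V replicate 3. Adhesion genes lower numbered 5 without V replicate 2 and 3 without V replicate 3. Genes of the p53 list higher numbered 4 without V replicate 1, 4 without V replicate 2 and 3 without V replicate 3. Glycolysis genes higher numbered 3 without V replicate 2 and 3 without V replicate 3. Neutrophil markers lower numbered 3 without D1 replicate 2, 8 without V replicate 1, 4 without V replicate 2 and 6 without V replicate 3.

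tVk12653 against WT describes a single transplantable Vκ*MYC line, so its 2 recipients speak for that line. It held more Myc RNA than any other group (7946 ± 178 CPM against 52.0 ± 18.6, 7.26 ± 0.43, adjusted p = 4.79e-05), with Mycn higher as well (49.8 ± 6.21 against 0.802 CPM, 5.96 ± 0.61, adjusted p = 3.10e-04). Rb1, the retinoblastoma tumour suppressor, was nearly absent (0.470 CPM against 137 ± 15.4, adjusted p = 6.21e-05). Map3k14, the kinase NIK of the alternative NF-kB pathway, was high (546 ± 46.2 against 26.3 ± 5.69 CPM, 4.38 ± 0.25, adjusted p = 4.79e-05). edgeR called 1501 genes higher and 1868 lower of 11933. Bche (butyrylcholinesterase), Nt5el and the RNA export factor Nxf3 were at 0 in every WT library and at least 92.1-fold, 82.1-fold and 45.0-fold higher, and Rfx6, a transcription factor of the endocrine pancreas, stood at 167 ± 17.1 CPM against 0.115. Sis (sucrase-isomaltase) and Igsf10 reached 296 and 301 CPM from 0.0926 and 0.236. The TGF-beta receptor Tgfbr2, thrombomodulin Thbd, the inhibitory receptor Btla, the kinase Fyn, Cd180 and Samsn1 were at 0 in both recipients, at least 169-, 134-, 121-, 82.0-, 73.9- and 72.2-fold lower. St6gal1, a sialyltransferase, went from 1129 ± 402 to 0.470 CPM, and Egr1, an immediate early gene, from 559 ± 424 to 0.357 CPM. MYC targets rose in 15 of 30 (20 and 0 over the list alone, camera adjusted p = 1.61e-06, adjusted p = 0.336 with an estimated correlation), Fbl at 1.71 ± 0.32. Oxidative phosphorylation genes rose in 14 with 1 lower of 28 (16 and 1 over the list alone, camera adjusted p = 1.18e-04, adjusted p = 0.323 with an estimated correlation). Of proliferation genes 1 of 28 rose, Foxm1 (0 and 0 over the list alone, camera adjusted p = 0.0311, adjusted p = 0.710 with an estimated correlation). Of DNA replication genes 2 of 28 rose, Mcm6 and Prim1 (0 and 0 over the list alone, camera adjusted p = 0.0392, adjusted p = 0.710 with an estimated correlation). Interferon response genes fell in 9 of 22 (0 and 10 over the list alone, camera adjusted p = 2.17e-05, adjusted p = 0.325 with an estimated correlation), Cmpk2 from 17.6 to 0.404 CPM. Plasma cell identity genes fell in 7 of 22 (1 and 10 over the list alone, camera adjusted p = 0.0206, adjusted p = 0.327 with an estimated correlation), among them Mzb1 (-5.48 ± 1.70) and the survival receptor Cd28 (-4.45 ± 0.52). Adhesion and homing genes fell in 10 of 21 (1 and 10 over the list alone, camera adjusted p = 0.00492, adjusted p = 0.323 with an estimated correlation). MHC class I genes rose in 4 and fell in 1 of 15 (4 and 1 over the list alone, camera adjusted p = 0.0903), with H2-K1 at 4377 ± 663 against 1410.3 ± 212 CPM. Genes of the p53 list rose in 8 and fell in 2 of 17 (9 and 2 over the list alone, camera adjusted p = 0.00827, adjusted p = 0.327 with an estimated correlation). Unfolded protein response genes rose in 2 and fell in 5 of 22 (2 and 5 over the list alone, camera adjusted p = 0.264), Sel1l at 1.89 ± 0.40 and Calr at -1.26 ± 0.35. Glycolysis genes rose in 4 and fell in 3 of 16 (4 and 3 over the list alone, camera adjusted p = 0.372) and had a median of 0.37 and a mean of -0.09. Neutrophil, B cell and erythroid markers fell in 17 of 19, 11 of 16 and 12 of 13 cases (18, 16 and 12 over the list alone, camera adjusted p = 1.36e-08, 1.36e-08 and 1.27e-06, adjusted p = 0.323 with an estimated correlation, 0.318 and 0.323 in turn). With a single recipient, where the other arms gave the spread, genes higher and lower numbered 671 and 587 (without replicate 1) or 514 and 573 (without replicate 2). Leaving out WT replicate 1, 2 or 3 gave 996, 931 and 903 genes higher. MYC targets higher numbered 7 without WT replicate 1, 7 without WT replicate 2, 9 without WT replicate 3, 4 without tVk12653 replicate 1 and 2 without tVk12653 replicate 2. Oxidative phosphorylation genes higher numbered 9 without WT replicate 1, 6 without tVk12653 replicate 1 and 4 without tVk12653 replicate 2. Interferon response genes lower numbered 3 without tVk12653 replicate 1 and 4 without tVk12653 replicate 2. Identity genes of plasma cells lower numbered 4 without WT replicate 3, 3 without tVk12653 replicate 1 and 3 without tVk12653 replicate 2. Adhesion genes lower numbered 3 without tVk12653 replicate 1 and 3 without tVk12653 replicate 2. MHC class I genes higher numbered 2 without WT replicate 1, 2 without WT replicate 2, 2 without WT replicate 3 and 2 without tVk12653 replicate 2. Genes of the p53 list higher numbered 4 without tVk12653 replicate 1 and 5 without tVk12653 replicate 2. Unfolded protein response genes lower numbered 2 without tVk12653 replicate 1 and 2 without tVk12653 replicate 2. Glycolysis genes higher numbered 2 without tVk12653 replicate 1 and 0 without tVk12653 replicate 2. Neutrophil markers lower numbered 2 without tVk12653 replicate 1 and 3 without tVk12653 replicate 2. B cell markers lower numbered 5 without tVk12653 replicate 1 and 5 without tVk12653 replicate 2. Erythroid markers lower numbered 4 without tVk12653 replicate 1 and 3 without tVk12653 replicate 2.

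VQ against tVk12653 sets tumours with mutant Nras against a Vκ*MYC tumour line, all from transplant recipients. Myc and Map3k14 were lower in VQ and Spry4 was higher, while most genes of each list did not pass when adjusted over all genes tested. edgeR called 712 genes higher and 500 lower of 11933. The median log2 fold change of all genes was 0.18 (0.11 with relative log expression scaling), and changes here are to be read relative to it. Spry4 stood at 79.6, 34.1 and 222 CPM in the 3 lines and 0.178 in tVk12653, Spred1, another inhibitor of the pathway, at 0.555, 68.8 and 173 against 0.291, and Egr1 at 59.3, 423 and 137 against 0.357. RAS-ERK output genes rose in 5 of 18 with 0 lower (10 and 0 over the list alone, camera adjusted p = 0.00492, adjusted p = 0.960 with an estimated correlation). Nras itself did not pass (0.79 ± 0.45, adjusted p = 0.269). MYC targets rose in 9 of 30 (18 and 0 over the list alone, camera adjusted p = 1.47e-04, adjusted p = 0.960 with an estimated correlation), Srm at 1.69 ± 0.40, while Myc fell (-2.58 ± 0.36, adjusted p = 0.00394). Unfolded protein response and chaperone genes rose in 6 of 22 (12 and 1 over the list alone, camera adjusted p = 0.00492, adjusted p = 0.960 with an estimated correlation), with calreticulin Calr at 1.63 ± 0.35 and Dnajc3 at 1.72 ± 0.19. MHC class I genes fell in 5 of 15 and rose in 1 (1 and 5 over the list alone, camera adjusted p = 0.01003, adjusted p = 0.960 with an estimated correlation), B2m at -2.01 ± 0.51. Interferon response genes rose in 4 of 22 (6 and 0 over the list alone, camera adjusted p = 0.0124, adjusted p = 0.960 with an estimated correlation), Bst2 at 1.25 ± 0.32. Map3k14 (-6.25 ± 0.27, adjusted p = 6.26e-06) and the apoptosis inhibitor Birc3 (-1.72 ± 0.25) were the 2 of 16 NF-kB targets that fell (0 and 2 over the list alone, camera adjusted p = 2.55e-05, adjusted p = 0.960 with an estimated correlation). Rb1 stood at 302, 155 and 153 CPM against 0.470 (adjusted p = 7.36e-05), and Bcl2 was lower (-4.41 ± 1.09, adjusted p = 0.0338), though D1 held more Bcl2 than D5. The intermediate filament nestin Nes, Fyn, Lamb1 and Dnajc15, a mitochondrial co-chaperone, were at 0 in both tVk12653 recipients, so that VQ was at least 412-, 354-, 169- and 77.1-fold higher, and the heparanase gene Hpse and the tetraspanin Cd63 at least 44.3- and 29.3-fold. Rfx6 and Nt5el were at 0 in every VQ library, at least 274- and 133-fold lower, and Gpr158, Cd109, monoamine oxidase Maoa and Hoxa7 were under 1 CPM in each line against 163, 91.4, 32.0 and 70.5 CPM. No neutrophil, B cell or erythroid marker passed (0 of 19, 0 of 16 and 0 of 13, none adjusted over the list alone). With tVk12653 replicate 1 or 2 left out, which leaves a single library in that arm and takes the spread from the other arms, edgeR called 64 and 136 or 49 and 89 genes. Without D4 there were 1177 genes higher, and in a fit of these 2 arms alone 7 and 19 genes. RAS-ERK genes higher numbered 0 without tVk12653 replicate 1 and 0 without tVk12653 replicate 2. MYC targets higher numbered 17 without D4, 0 without tVk12653 replicate 1 and 0 without tVk12653 replicate 2. Unfolded protein response genes higher numbered 1 without tVk12653 replicate 1 and 1 without tVk12653 replicate 2. MHC class I genes lower numbered 3 without D4, 1 without tVk12653 replicate 1 and 0 without tVk12653 replicate 2. Interferon response genes higher numbered 2 without D5 replicate 2, 0 without tVk12653 replicate 1 and 0 without tVk12653 replicate 2.

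VQ D1 against VQ D5 compares lines of the same genotype, with 2 recipients each, and the tumours differed widely. D5 recipients held more Nras, Myc and Ccnd1 RNA, and D1 recipients more Ccnd2, Cd74 and Ptprc RNA. edgeR called 2568 genes higher in D1 and 2783 lower of 12835, 41.7% of those tested. The cyclin genes Ccnd1 and Ccnd2 differed in opposite directions. Ccnd1 (chromosome 7, 144929931 to 144939831) stood at 0.270 and 0.217 CPM in D1 and 52.6 and 37.0 in D5 (adjusted p = 2.70e-04). Ccnd2 (chromosome 6, 127125162 to 127152188) stood at 2207 and 3342 CPM in D1 and 28.8 and 142 in D5 (5.02 ± 1.25, adjusted p = 0.0137). D4 held 15.8 CPM of Ccnd1 and 3325 of Ccnd2, so both D4 and D5 held RNA of the 2 cyclins. Cd74 (chromosome 18, 60803849 to 60812652), the invariant chain that guides MHC class II, stood at 3258 and 2511 CPM in D1 and 3.96 and 11.2 in D5 (8.55 ± 0.42, adjusted p = 4.63e-08). Ptprc was also higher in D1 (5.92 ± 0.34, adjusted p = 9.13e-08). Nras was lower in D1 (-1.76 ± 0.17, adjusted p = 1.50e-06), as was Myc (-0.93 ± 0.26, adjusted p = 0.0123), and Sdc1 was higher (1.17 ± 0.27, adjusted p = 0.00435). Proliferation genes were lower in D1 in 18 of 28 cases (0 and 20 over the list alone, camera adjusted p = 1.43e-04, adjusted p = 0.726 with an estimated correlation). DNA replication genes were lower in 14 with 1 higher of 28 (1 and 14 over the list alone, camera adjusted p = 0.00134, adjusted p = 0.726 with an estimated correlation). MYC targets were lower in 20 of 30 (0 and 20 over the list alone, camera adjusted p = 5.66e-05, adjusted p = 0.721 with an estimated correlation). RAS-ERK output genes were lower in 9 and higher in 2 of 20 (2 and 10 over the list alone, camera adjusted p = 0.112). Dusp4, a phosphatase that acts on ERK, was at 0 in both D1 recipients, at least 53.3-fold lower, and Spred1 stood at 1.08 and 0.326 CPM in D1 and 158 and 169 in D5. NF-kB targets were higher in D1 in 12 and lower in 2 of 16 (12 and 2 over the list alone, camera adjusted p = 1.32e-04, adjusted p = 0.288 with an estimated correlation). The inhibitor Tnfaip3 (A20) stood at 189.8 and 119 CPM in D1 and 1.06 and 1.79 in D5, and Relb at 43.7 and 26.9 in D1 and 0 and 1.02 in D5. MHC class I genes were higher in 10 and lower in 1 of 15 (11 and 1 over the list alone, camera adjusted p = 0.00113, adjusted p = 0.726 with an estimated correlation), such as Tapbp (2.83 ± 0.18) and B2m (2.41 ± 0.20). MHC class II genes were higher in 6 of 10 (7 and 0 over the list alone, camera adjusted p = 0.00173, adjusted p = 0.726 with an estimated correlation). Interferon response genes were higher in 11 of 23 (13 and 0 over the list alone, camera adjusted p = 5.10e-04, adjusted p = 0.721 with an estimated correlation). In the BCL2 family Bcl2 (6.24 ± 0.59) and Bcl2l1 (5.05 ± 0.52), which block apoptosis, were higher in D1, and Bcl2l11 (BIM), which promotes it, was lower (-3.15 ± 0.25). In that list 4 were higher and 2 lower of 13 (4 and 2 over the list alone, camera adjusted p = 0.532). Unfolded protein response genes were higher in 2 and lower in 10 of 22 (2 and 10 over the list alone, camera adjusted p = 0.0919). ATF4 genes were higher in 7 and lower in 4 of 17 (7 and 4 over the list alone), including Slc3a2 (3.04 ± 0.31). Genes of plasma cell identity were higher in 6 and lower in 4 of 22 (6 and 4 over the list alone, median 0.29 and mean -0.24), including Tnfrsf17, which encodes BCMA (-3.87 ± 0.42). The cadherin Cdh19 and Esrp1, a regulator of epithelial splicing, were at 0 in both D5 recipients, so D1 was at least 404- and 97.9-fold higher, and Ly6d stood at 566 and 574 CPM in D1 and 0 and 0.255 in D5. The fatty acid carrier Fabp5, the disulphide isomerase Pdia5 and the receptor Ryk were at 0 in both D1 recipients, at least 271-, 237- and 126-fold lower. Neutrophil markers were higher in D1 in 11 of 19 (12 and 0 over the list alone, camera adjusted p = 3.24e-04, adjusted p = 0.726 with an estimated correlation) beside these groups. Monocyte markers were higher in 4 with 1 lower of 17 (3 and 1 over the list alone, camera adjusted p = 0.0147, adjusted p = 0.726 with an estimated correlation). Proliferation genes lower numbered 9 without D1 replicate 1 and 11 without D5 replicate 2. Interferon response genes higher numbered 7 without D5 replicate 2. Unfolded protein response genes lower numbered 6 without D1 replicate 2 and 6 without D5 replicate 1. Identity genes of plasma cells higher numbered 3 without D1 replicate 1, 3 without D5 replicate 1 and 3 without D5 replicate 2. Identity genes of plasma cells lower numbered 2 without D1 replicate 2 and 2 without D5 replicate 1. Neutrophil markers higher numbered 3 without D1 replicate 1, 1 without D5 replicate 1 and 6 without D5 replicate 2.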

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

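The items of this part were picked after their values were seen, and the test of other cells in the Ptprc pattern was also chosen after seeing the result. D1 and D5 are lines of the same genotype, and each difference was tested directly between them with edgeR. Against WT, 6589 genes were called in D1 and 7526 in D5, 4175 in both in the same direction, and 552 changed in opposite directions and also differed between the lines. Ccnd1, a D-type cyclin that drives entry into the cell cycle, had a log2 fold change of -7.41 (D1 minus D5), and its relative Ccnd2 of 5.02. Nras differed by -1.76, although both lines carry the same engineered allele, and the counts do not tell which allele the RNA came from. Nras lies on chromosome 3, whose genes were shifted by 0.55 (log2, relative to WT) in D5, and a link between the 2 was not tested. Cd74 differed by 8.55 and Ptprc by 5.92. The list of MHC class II genes had a median of 2.78 (2.64 with genes at 0 in a line set to their bound), and that of NF-kB targets 2.99 (2.44).

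Ptprc encodes CD45, on which the cells of all groups were sorted per the series description, yet its RNA was near 0 in D4 (1.68 CPM) and D5 (1.85 and 6.63 CPM) against 547, 800.0 and 604 CPM in WT. The counts do not show whether that gate was used for D4 and D5, and without it the low RNA would not be at odds with the sort. Cells other than plasma cells in those sorts would lack plasma cell RNA, and would have to lower all of it about as far as Ptprc (log2 ratio to WT -7.89 in D4 and -6.83 in D5). Irf4, Xbp1, Sdc1 and Prdm1 had a pooled median of 0.24, with 0.86, 0.35, 0.71 and 0.19 in D4 and 0.30, -0.55, -1.04 and -1.26 in D5, which argues against that as the whole cause, although Jchain, Mzb1 and Cd38 stood at 43.7, 0.552 and 0 CPM in D4 against means of 44151, 305 and 22.9 CPM in WT. The 4 genes were picked after the pattern was seen. Loss of the chromosome region would lower its neighbours too, and the median of the 10 nearest expressed genes was -0.17. This argues against a loss that reaches those genes. The nearest on either side, Nek7 and Zfp281, start at 420978 and -1437958 bp from Ptprc. A smaller loss, within the gene or of the whole gene and its surroundings short of these neighbours, stays open. A biological difference between the lines may underlie the pattern, and no test of it was made.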

How the results depend on the processing

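The alternatives added after seeing the data were removal of X and Y genes, WT replicate 2 and D1 replicate 1 both left out, the fit without the VQ lines and the block in a fit of V and WT alone, with all pairs or each left out, and the others were planned. Counts below are genes called higher and lower. For V against WT edgeR gave 0 and 0, with 628 genes at an unadjusted p under 0.05, about the share that chance alone would give. The counts were 1 and 2 without the filter, 10 and 32 with DESeq2 and 1 and 1 with the 2 arms alone. They were 1 and 2 with all libraries and a mean per arm, 17 and 7 with a mean per group and 1 and 4 without the VQ lines. For VQ against WT (2065 and 1807) they were 1831 and 1967 with relative log expression factors and 2099 and 2359 with DESeq2. They were 1064 and 976 with the 2 arms alone and 3130 and 4229 with a mean per group, and with a library left out 1140 to 2367 higher and 1285 to 1961 lower. For tVk12653 against WT (1501 and 1868) they were 2422 and 2742 with the 2 arms alone, 2886 and 3362 with a mean per group and, without the VQ lines, 2590 and 3003. They were 908 and 1252 with WT replicate 2 and D1 replicate 1 left out, and 514 to 996 and 573 to 1360 with a library left out. For VQ against V (1865 and 1474) they were 738 and 760 with the 2 arms alone, 2991 and 3894 with a mean per group, and 857 to 2207 and 837 to 1615 with a library left out. For VQ against tVk12653 (712 and 500) they were 1137 and 849 with DESeq2, 7 and 19 with the 2 arms alone, 838 and 779 with a mean per arm and 2319 and 2709 with a mean per group. Without line D1 they were 1136 and 867, without line D5 871 and 861, and with a library left out 49 to 1177 and 89 to 725. For D1 against D5 (2568 and 2783) a log2 fold change of at least 1 left 1773 and 1766, and leaving out a library gave 1763 to 2042 and 2070 to 2159. Fits of all libraries, with a mean per arm or per group, treat recipients of a VQ line as independent, which the main fit of arms does not. The 2 tVk12653 recipients are separate units in that fit too. D1 against D5 rests on recipients of each line, so it speaks for these lines only. In fits with a mean per group, without and with the block, 3 results that had not been called changed sign: Cox6a2 log2 fold change, VQ vs WT, to -1.21 and -1.32, Cox6a2 log2 fold change, VQ vs V, to -2.05 and -2.16, and Kitl log2 fold change, VQ vs tVk12653, to -1.46 and -1.53. Of named genes under single alternatives, 11053 results were the same, 874 weaker, 152 stronger and 6 reversed, and of lists under an alternative set test 77 were the same and 85 weaker. Alternatives without immunoglobulin genes were not run, since the table holds no such segments. The causes of these differences were not tested.

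Pairing by replicate number exceeded a correlation of 0.1 between WT and V alone. V and tVk12653 libraries had smaller values in the same direction, 0.0845 to 0.0911 for the same number and -0.0911 to 0.00933 for different numbers. In a group of 2 libraries the deviations mirror each other, so the check says little for such groups. With the number as a block, V against WT gave 43 and 48 genes in the fit of all libraries with a mean per group (17 and 7 without the block). In the fit of V and WT alone the block gave 138 and 341 (1 and 1 without it). That blocked fit gave 211 and 480, 47 and 85 and 124 and 478 without pair 1, 2 or 3. Elsewhere the block in the fit with a mean per group gave 2946 and 3947 in VQ against WT and 2724 and 3241 in tVk12653 against WT. It gave 2808 and 3609 in VQ against V, 2389 and 2695 in VQ against tVk12653 and 2567 and 2855 in D1 against D5. The same fit without the block gave, in turn, 3130 and 4229, 2886 and 3362, 2991 and 3894, 2319 and 2709 and 2568 and 2783.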

Other observations

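The tests of marker genes among the genes lower in VQ, of chromosome shifts against V, and of the shifted chromosomes with chromosome 3 of D5 left out were chosen only after the result was seen, as were the counts of silent genes and of genes shared between tumours. Many genes of normal plasma cells were silent in a tumour line. Of 5912 genes at 20 CPM or more in every WT and V library, 47 were at 1 CPM or less in every D1 library, 99 in D4, 63 in D5 and 83 in tVk12653. D4 had to meet this cut in a single library and each other group in all of its libraries, so the D4 count is not on equal terms. Those silent in all 4 included the B cell receptor signalling genes Cd79a and Blk, the IgM receptor Fcmr and the homing receptor Ccr9. Mzb1, Irf8 and Runx3 were silent in D4 alone of these groups, Rb1, Tgfbr2 and Egr1 in tVk12653 alone, Il2rg, H2-Eb1 and Runx2 in D5 alone, and Zhx2 and Ctsc in D1 alone.

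VQ and tVk12653 shared many changes against WT: 877 genes rose in both and 1118 fell in both, with 39 in opposite directions. If the 2 comparisons were independent, 259.7 and 283 would be expected. They are not independent: both use the same WT libraries, which alone gave a correlation of 0.466 in 20 simulations, against 0.744 observed. The covariance was 2.05 against 0.153 simulated. Markers of other cells fell against WT in both arms, and both arms came from transplant recipients. How much of the overlap these account for was not tested.

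Genes lower in VQ than in WT may in part reflect RNA of other cell types in the WT sorts, which the B220 gate should limit for B cells. The median V minus WT log2 fold change was -1.43 for the 75 marker genes among them, and -0.52 for the 67 of these tested without WT replicate 2, so for them this stays open. For all 1807 it was -0.21 (bootstrap interval over genes -0.24 to -0.19, and -0.14 without WT replicate 2). This argues against RNA held by the WT but not the V sorts as the whole cause. V sorts hold RNA of other cell types too, so a share of such RNA common to WT and V stays open. Fewer plasma cell transcripts in the tumours stay open: 71.0% of those genes were also lower in VQ than in V, but V sorts hold more neutrophil marker RNA than VQ too, a reading set after the value was seen.

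Genes of some chromosomes were shifted together in the tumour lines, and some of these shifts were shared between lines. Chromosomes 5 and 8 were lower in D1 (-0.87 and -0.81, log2), 5 was lower and 15 higher in D4 (-0.93 and 0.71), 3 higher in D5 (0.55), and 7 higher with 8 and 14 lower in tVk12653 (0.79, -0.77 and -0.78). No WT or V library exceeded 0.121 in size, but the WT mean is the reference, which holds WT values near 0. Only shifts of at least 0.5 in size are listed. The largest of the other tumour line and chromosome pairs was 0.287 in size (chromosome 10 in tVk12653, -0.294 and -0.279 in its recipients). All 8 shifts stayed after correction for GC content and length of the transcripts, which argues against composition bias. All 8 also stayed against V, which argues against RNA of other cell types held by the WT but not the V sorts. V sorts hold such RNA too, so RNA common to WT and V was not tested. Gain or loss of whole chromosomes is a candidate explanation: the smallest shift of any part, with each chromosome in 3 parts, was 0.61 once chromosome 3 of D5 was left out. With it the value was 0.20, so whole and partial gain cannot be told apart there, and DNA was not analysed here.

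Regrouping 6 units as 3 against 3 allows 10 splits, too few for a share under 0.05. For V against WT all 10 splits gave as many genes as the real 0 (edgeR, highest other 0). Any split meets a count of 0, so this decides nothing there. In the real grouping 628 genes had an unadjusted p under 0.05, about the share that chance alone would give, and DESeq2 called 10 and 32. The splits used no replicate block, and the blocked fits that called genes were not regrouped. For VQ against WT and VQ against V, 1 and 1 split, the real ones, gave as many as 3872 and 3339, and the highest others gave 0 and 0.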
